A study of Mus musculus with 24 samples.

How the data were processed

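The 24 libraries were grouped by the line, treatment and fraction in their labels, 2 per group. Per the labels' protocols, RNA was extracted with Trizol and sequenced as paired-end TruSeq libraries of polyadenylated RNA. The aligner, counting method, genome build, normalization and statistical model are not given in the sources used here. What was analysed is the authors' comparison table with 13504 genes, each with a symbol, a gene identifier and a transcript identifier; all of them matched GENCODE M21 (GRCm38) by identifier, a release that was used for coordinates, lengths and sequences here and may differ from the annotation the authors used. Per the file headers, the deposited log fold change and average expression are on a log scale, read here as log2 because the column names are those of a limma results table, although no base is stated. Per the file headers, each line also has a deposited p-value and adjusted p-value, the smallest of which correspond to 15864 genes tested by the authors, more than the table holds. Average expression was identical in both columns, as it would be if a common model held both lines. A further deposited column names the 222 genes that passed adjusted p of 0.05 in the Rps26Tir1 line and not in the other, and it matched the adjusted p-values for every gene.

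The tests planned before the data were examined needed counts or normalized values per library: heavy against free fractions, the effect of IAA within each fraction, its effect on the heavy to free ratio, differences between the lines before treatment, and values of each replicate. None of these was run, and the deposited statistics were used instead. The genes named were set by a rule fixed in advance: Rack1 and Rps26, the 12 positive and 12 negative genes with the largest absolute fold change among those with adjusted p under 0.05 and average expression of at least 3, and up to 4 members of each list with the smallest p. Its further condition, the same sign in each replicate, was not applied because it needs values per library. Unnamed gene models were counted and not named, and some list members are not reported here. Rnaset2b, Rnaset2a, Rps27rt and the Srsf genes were chosen after their values were seen, as were Nnt and Ptp4a1. In addition, 11 gene families, 10 defined by symbol and 1 by a hydrophobic N-terminus, were inspected after seeing the data and tested together.

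A t-statistic was worked back from each p-value and the sign of the fold change, and the standard error is the fold change divided by it. The degrees of freedom were estimated as the whole number from 8 to 60 at which the ratio of the standard errors of the lines varied least between genes with average expression of at least 3, which gave 29. The difference between the lines was tested with a moderated-t form of statistic, (Rps26Tir1 minus FreeTir1) over the root of the summed squared standard errors, two-sided, with Benjamini-Hochberg adjustment over 13504 genes. This takes the errors of the lines as independent. Separate libraries for each line are needed for that but are not enough, since libraries of different lines can share errors. The procedure was tested on simulated data: 24 libraries of 13504 genes were drawn with the deposited expression levels and a spread matched to the deposited standard errors, and fitted with limma, and changes were planted in the Rps26Tir1 line in 200 genes. In that simulation the estimate was 27 degrees of freedom where the model had 27.4. Each simulated gene had the same standard error in both lines, so the estimate had to recover that value. It is not checked for standard errors that differ between the lines, as the deposited ones do. The simulated errors of the lines were independent, so the simulation does not check that assumption. The difference test found 17 of 67 genes planted at 0.5, 63 of 67 at 1 and 66 of 66 at 2 on the log2 scale, with 4 false calls. All planted genes had average expression of at least 3, so these counts do not cover genes below that. Median standard errors in the Rps26Tir1 line were 0.115 at 3 and above, 0.168 from 1 to 3 and 0.363 below 1. The simulated comparison averaged the 3 fractions equally, which the authors' comparison may not have done.

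Of 32 gene lists written before the data were examined, 29 had at least 3 measured members. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on signed normal scores of the p-values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. In the simulated Rps26Tir1 line, 2 of 200 lists drawn without a change had p under 0.05; genes were simulated independently, so this does not check the preset correlation. List medians were also placed among 10000 random lists of the same size matched on average expression. Transcript features were computed with Python 3.11.15 from the transcript each row names, and the share of its 31-base stretches found in transcripts of other genes, on the same strand, was counted. Alternatives covered the adjusted p threshold, a minimum absolute fold change of 1, a minimum average expression of 1 or 3, the adjustment over the rows of the table, genes with over 50% shared sequence, centring, removal of the trend with length, GC content and expression, the degrees of freedom (20 and 40), and the form of the set test. Except for the minimum fold change these were chosen after seeing the data. FreeTir1 values of the 222 genes were also drawn 1000 times from the linear relation between the lines, and its residuals, among the other genes of similar average expression, a test chosen after the result was seen.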

Results

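Polysome profiling followed by RNA sequencing was carried out on mouse E14 embryonic stem cells in which RACK1, a protein of the small ribosomal subunit, carried an auxin-inducible degron (AID). In such cells the plant hormone indole-3-acetic acid (IAA) brings a tagged protein to the F-box receptor TIR1, which marks it for degradation. In the Rps26Tir1 line TIR1 was joined to the ribosomal protein RPS26, and in the FreeTir1 line TIR1 was not attached to the ribosome. Each line was treated for 12 h with IAA or with DMSO, and polyadenylated RNA was sequenced from free, low-translation and heavy-translation fractions, which gave 24 libraries in 12 groups of 2. The labels do not say whether the 2 replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries.

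The values available were the authors' own comparison of IAA and DMSO in each line, for 13504 protein-coding genes, with a log fold change, an average expression, a p-value and an adjusted p per gene. No value per library was used here, so the read depth behind each gene is unknown and no mean, SD or fraction-specific level can be given. The column names do not state which fractions entered the fold change, nor which treatment was its numerator. Values are therefore given as positive or negative: under the usual order of IAA over DMSO, a positive value would be higher with IAA. A change of transcript amount and a change of ribosome loading are not separated by these values.

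The first comparison asked whether mRNA of the tagged protein and of the TIR1 fusion partner differed between treatments. In the authors' deposited table, Rack1 (chromosome 11, 48800332 to 48806434, GRCm38) had a log fold change of 0.19 in the FreeTir1 line with adjusted p = 0.818. Its value in the Rps26Tir1 line of the authors' deposited table was -0.05 with adjusted p = 0.892. For Rps26 (chromosome 10, 128624534 to 128626747) the authors' deposited table gave -0.16 with adjusted p = 0.840 and 0.06 with adjusted p = 0.843 in the FreeTir1 and Rps26Tir1 lines. Neither mRNA passed the threshold, and since the degron acts on protein these values do not test the depletion. Of the 31-base stretches of the Rps26 transcript, 45.5% also occur in transcripts of other genes, so its reads could be divided among copies.

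The second comparison asked which mRNAs differed between IAA and DMSO in each line. In the Rps26Tir1 line, the authors' deposited table held 222 genes with adjusted p under 0.05, of which 149 were positive and 73 negative. Ppp1r10, which encodes a nuclear targeting subunit of protein phosphatase 1, had the smallest adjusted p of the authors' deposited table, 6.67e-05, with a log fold change of 1.25. The transcription factor gene Myc stood at 1.01 in the authors' deposited table with adjusted p = 0.00386. Lefty2, an antagonist of Nodal signalling, stood at -0.64 with adjusted p = 0.00267 in the authors' deposited table, and Fos, a component of AP-1, at -0.62 with adjusted p = 0.0133. In the FreeTir1 line, 0 genes of the authors' deposited table had adjusted p under 0.05, with a smallest value of 0.0778. At an unadjusted p under 0.05 the authors' deposited table held 904 genes (6.69%) for FreeTir1 and 2198 genes (16.3%) for Rps26Tir1.

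Among the 222 genes, 130 had an average expression of at least 3. Ppp1r10 and Myc were among the 12 named genes with the largest positive values of these. Arid5b, an AT-rich interaction domain protein, stood at 0.83 in the authors' deposited table, and Id3, an inhibitor of basic helix-loop-helix factors, at 0.76. The histone H3 lysine 4 methyltransferase gene Setd1b stood at 0.75 in the authors' deposited table. Hrk, a pro-apoptotic BH3-only gene, had 0.74, the replication initiation gene Ticrr 0.80 and the diacylglycerol kinase gene Dgke 0.74 in the authors' deposited table. Inka2, Tnks1bp1, Kank4 and Edrf1 filled the remaining places, at 1.05, 0.87, 0.76 and 0.73 in the authors' deposited table.

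The 12 genes with the largest negative values were led by Rps27, a small-subunit ribosomal protein gene, at -1.33 in the authors' deposited table. Of the 31-base stretches of the Rps27 transcript 98.7% also occur in other genes, so this value is uncertain. Its expressed copy Rps27rt had -0.17 with adjusted p = 0.533 in the authors' deposited table. The Wnt acyltransferase gene Porcn had -0.70, the lysosomal Plbd2 -0.56, the mitochondrial rRNA chaperone gene Eral1 -0.57 and the peroxisomal protease gene Tysnd1 -0.50 in the authors' deposited table. Besides Lefty2 and Fos, Tprn stood at -0.65, Irf2bp1 at -0.59, Ier3 at -0.56, Aunip at -0.52 and Nfil3 at -0.51 in the authors' deposited table. Standard errors worked back from the p-values of these 24 genes ranged from 0.101 to 0.288 in the Rps26Tir1 line. The calls of Irf2bp1, Ier3 and Tysnd1 ended when only genes with average expression of at least 3 were adjusted together, with adjusted p = 0.0555 for each. That of Ier3 also ended, at 0.0503, when the adjustment was recomputed over the genes in the table. With the trend in length, GC content and expression removed, the calls of Setd1b, Eral1, Nfil3, Irf2bp1, Ier3 and Tysnd1 ended, at 0.0544, 0.0713, 0.0700, 0.0757, 0.1 and 0.0939.

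Gene groups fixed in advance were compared with all other genes by cameraPR of limma, a set test, on the signed statistics. In the Rps26Tir1 line, p53 targets were shifted to positive values: 19 of 22 measured members were positive, the median was 0.24 and the set test gave adjusted p = 4.25e-05. Btg2, an antiproliferative gene, passed on its own with 0.44 and adjusted p = 0.0370 in the authors' deposited table, and 10 members passed when adjusted over the list alone, all of them positive. Zmat3 at 0.34, Sesn2 at 0.48 and Plk2 at 0.47 did not pass over all genes in the authors' deposited table, with adjusted p of 0.0602, 0.0655 and 0.0719. In the FreeTir1 line 15 of the 22 were positive, with a median of 0.03 and adjusted p = 0.682 in the set test.

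Proteasome subunits were shifted to negative values in the Rps26Tir1 line, with 28 of 37 members negative, a median of -0.12 and adjusted p = 0.000602. No subunit passed over all genes, 1 passed when adjusted over the list alone, and Psmd11 had the smallest adjusted p in the authors' deposited table, 0.0507, at -0.38. Glycolysis genes had 14 of 16 members negative, with a median of -0.15 and adjusted p = 0.0243, and Pgam1 led them at -0.34 with adjusted p = 0.0728 in the authors' deposited table. Nuclear-encoded oxidative phosphorylation genes had 52 of 77 members negative, with a median of -0.05 and adjusted p = 0.0133. Uqcr10, a complex III subunit, stood at -0.37 with adjusted p = 0.0801 in the authors' deposited table. With a preset correlation of 0.05 in place of 0.01 the shifts of the proteasome, glycolysis and oxidative phosphorylation lists ended, with adjusted p of 0.0617, 0.196 and 0.232, whereas that of p53 targets held at 0.00622. An estimated correlation needs values per library and was not computed. Proteasome subunits leaned the same way in the FreeTir1 line, with 28 of 37 negative and a median of -0.06. The set test there gave adjusted p = 0.427, and 0.08% of the random lists had a median as low. The random lists were matched only on average expression. That share therefore makes no allowance for subunits that vary together and does not outweigh the set test. Glycolysis and oxidative phosphorylation genes had 8 of 16 and 31 of 77 members negative in the FreeTir1 line.

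Naive and general pluripotency genes were the list that passed in each line. In the FreeTir1 line 21 of 29 members were positive, with a median of 0.08 and adjusted p = 0.0143. In the Rps26Tir1 line 22 were positive, with a median of 0.13 and adjusted p = 0.0243. No member passed over all genes or when adjusted over the list alone in either line. Tbx3 stood at 0.29 with adjusted p = 0.140 in the Rps26Tir1 column of the authors' deposited table. Both shifts ended with a preset correlation of 0.05, at adjusted p of 0.317 and 0.232.

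The other 24 lists did not pass in either line, with adjusted p from 0.427 to 0.983 in the FreeTir1 line for all lists but pluripotency genes. Of 78 cytosolic ribosomal protein genes 50 were negative in the Rps26Tir1 line, with a median of -0.02 and adjusted p = 0.154, and Rps27 was the member that passed over all genes. Targets of the integrated stress response had a median of 0.01 over 31 genes with adjusted p = 0.736, and Chac1, a glutathione-degrading enzyme gene, passed at 0.72 with adjusted p = 0.0302 in the authors' deposited table. The 19 mRNAs regulated by upstream open reading frames had a median of 0.10 with adjusted p = 0.191 in the set test. Of these, Ppp1r15b, a regulatory subunit of the eIF2 alpha phosphatase, passed at 0.50 with adjusted p = 0.0463 in the authors' deposited table, where Atf4 stood at 0.30 with adjusted p = 0.102. Immediate early genes went both ways: 14 of 19 were positive with a median of 0.26 and adjusted p = 0.105, Myc was the member that passed with a positive value, and Fos and Ier3 passed with negative ones. Mesendoderm markers had a median of 0.00 and a mean of 0.19 over 8 genes, whereas the set test pointed to negative values with adjusted p = 0.279, and Lefty2 and Eomes passed, the latter at -0.62 with adjusted p = 0.0445 in the authors' deposited table. Primitive endoderm markers had 13 of 16 members negative with a median of -0.18 and adjusted p = 0.0553. Among fibroblast feeder cell markers, 6 of 10 were positive, with a median of 0.03, a mean of -0.02 and adjusted p = 0.744 toward negative values, and Col1a1 passed at -1.42 with adjusted p = 0.0254 in the authors' deposited table. Ribosome quality control and collision factors had a median of 0.04 over 34 genes with adjusted p = 0.769, and no member passed over all genes.

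Of the remaining lists in the Rps26Tir1 line, G2/M cell cycle genes had 15 of 17 members positive with a median of 0.18 and adjusted p = 0.0626. Mitochondrial ribosomal proteins had 49 of 78 members negative with a median of -0.04 and adjusted p = 0.0553. Ribosome biogenesis factors and unfolded protein response genes each had adjusted p = 0.138, with medians of 0.07 and 0.10. Cholesterol synthesis genes had adjusted p = 0.191, and Sc5d, a sterol desaturase gene, passed at -0.41 with adjusted p = 0.0423 in the authors' deposited table. Other 5' TOP mRNAs, translation initiation factors, neural markers and secretory translocation genes each had adjusted p = 0.324, with medians of -0.03, 0.03, 0.18 and -0.05. Nonsense-mediated decay factors, 2-cell-like markers and the 4 measured aryl hydrocarbon receptor targets each had adjusted p = 0.399. Heat shock chaperones and histones had medians of -0.02 and 0.00 but means of 0.09 and 0.11, with adjusted p of 0.736 and 0.673 toward positive values. Aminoacyl-tRNA synthetases and formative pluripotency genes had adjusted p of 0.849 and 0.910.

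**Figure D1:**
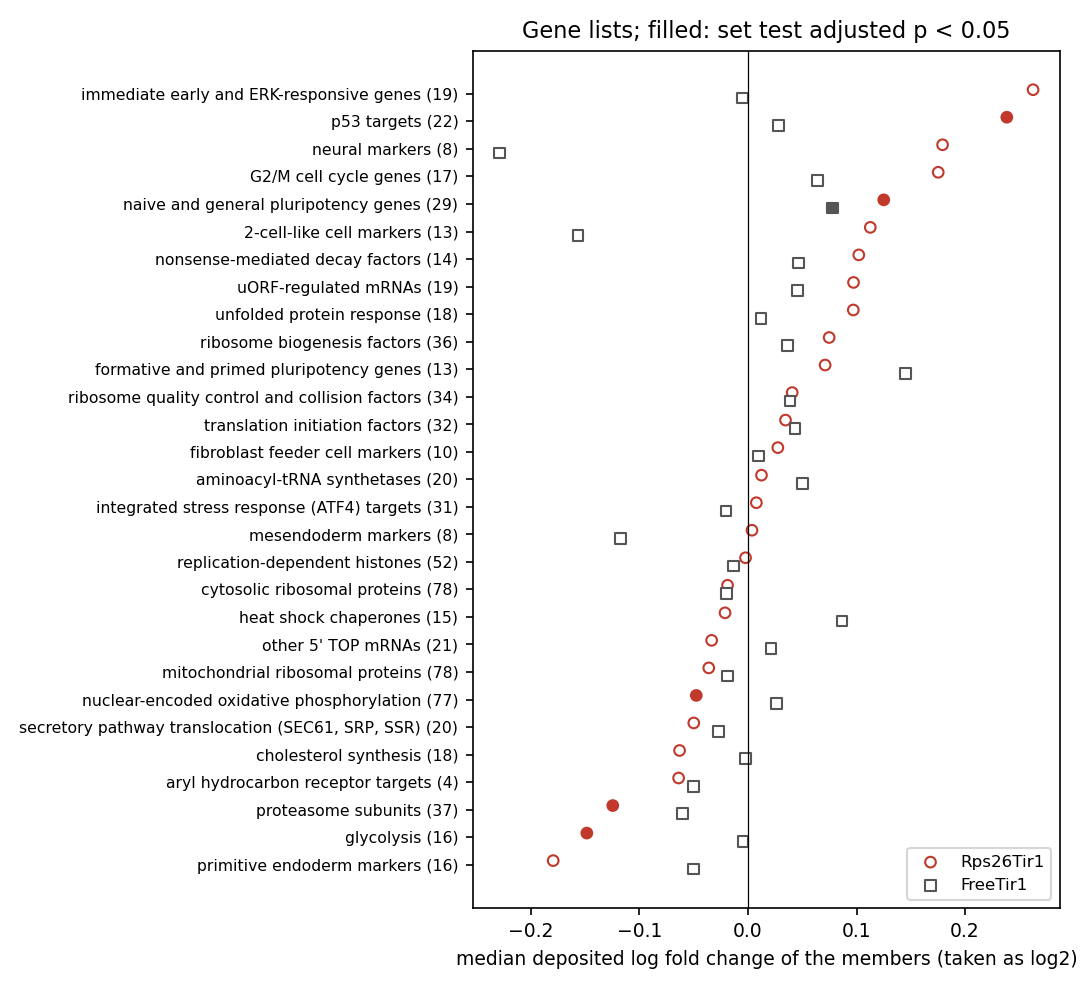
Median deposited log fold change (x axis, taken as log2) of the measured members of each of the 29 tested gene lists (y axis, number of members in brackets), with circles for the Rps26Tir1 line and squares for the FreeTir1 line; filled symbols passed the set test at adjusted p under 0.05. p53 targets have a median of 0.24 in the Rps26Tir1 line and 0.03 in the FreeTir1 line, and pluripotency genes are filled in both lines.

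The third comparison asked whether the effect of IAA differed between the lines, which the deposited label of 222 genes as significant in the Rps26 line alone does not test. Of these genes, 183 (82.4%) had the same sign in the FreeTir1 line, against 62.2% of all genes. The 149 positive genes had a median of 0.60 in the Rps26Tir1 line and 0.19 in the FreeTir1 line, and the 73 negative genes -0.62 and -0.21. The FreeTir1 value was positive for 126 of the former and negative for 57 of the latter. These genes, like the 24 named by size, were chosen by their Rps26Tir1 values, which by itself favours larger values in that line. Their medians therefore do not measure how far the lines differ. A test of the difference with standard errors worked back from the p-values found 1 gene with adjusted p under 0.05, and 835 genes at an unadjusted p under 0.05. The count of 1 became 0 with 20 degrees of freedom, with average expression of at least 3, without genes of over 50% shared sequence and with the trend in length, GC content and expression removed. It became 44 when the statistic was divided by 0.850, its spread over genes with average expression of at least 3. Of those 44, 39 had average expression below 3, where the spread was 1.22 for genes from 1 to 3 and 1.36 below 1. That division is therefore too small for most of them. The test takes the errors of the lines as independent, which these values do not establish. The gene was Rnaset2b, a ribonuclease gene (chromosome 17, 6970634 to 7011299, GRCm38), whose difference, Rps26Tir1 minus FreeTir1, was -2.36 with a standard error of 0.410 and adjusted p = 0.0414. Its average expression in the authors' deposited table was 2.06, and 91.6% of its 31-base stretches occur in other genes. For the 24 genes named by size the adjusted p of the difference lay between 0.310 and 0.9998, and the difference was 0.84 with a standard error of 0.230 for Myc and 0.75 with a standard error of 0.211 for Ppp1r10. Over all genes the fold changes of the lines had Pearson r = 0.06 and Spearman rho = 0.27, and over the 8633 genes with average expression of at least 3 these were 0.47 and 0.46. These are correlations across genes, which are not independent replicates.

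**Figure D2:**
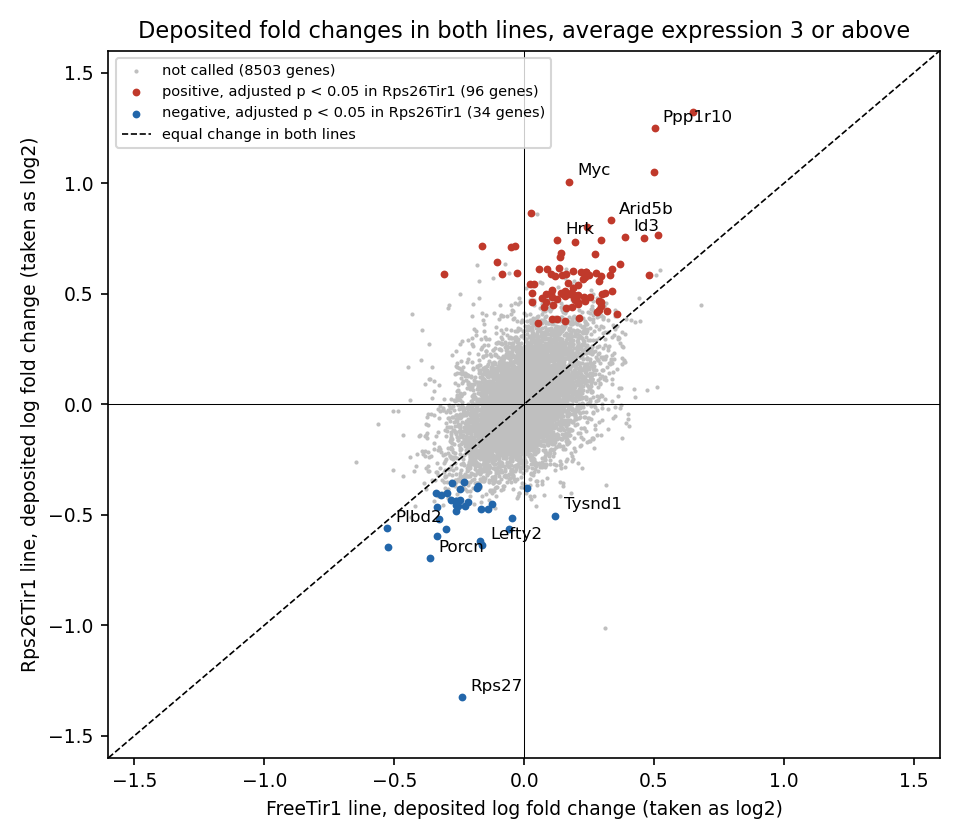
Deposited log fold change of IAA against DMSO (taken as log2; direction not stated in the column names) in the FreeTir1 line (x axis) and the Rps26Tir1 line (y axis) for 8633 genes with average expression of at least 3. Grey points are 8503 genes that did not pass, red points 96 positive and blue points 34 negative genes with adjusted p under 0.05 in the Rps26Tir1 line, and the dashed line marks an equal change; in the authors' deposited table Ppp1r10 lies at 0.50 and 1.25, Myc at 0.17 and 1.01, and Tysnd1 at 0.12 and -0.50.

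Gene lists were also tested for a difference between the lines. The difference was positive for 19 of 22 p53 targets, with a median of 0.25 and adjusted p = 0.000608. It was negative for 61 of 77 oxidative phosphorylation genes, with a median of -0.07 and adjusted p = 0.000608, and for 15 of 16 glycolysis genes, with a median of -0.14 and adjusted p = 0.0298. Proteasome subunits, with 28 of 37 negative, had adjusted p = 0.0524. Neural markers, with 6 of 8 positive and a median of 0.45, had the same adjusted p. With a preset correlation of 0.05 the p53 targets held at adjusted p = 0.0429, and oxidative phosphorylation and glycolysis genes were each at 0.143. Pluripotency genes had a median difference of 0.02 with adjusted p = 0.892.

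The fourth comparison related the fold change to the length of the mRNA, since RACK1 has been tied to the translation of short mRNAs. Across genes, Spearman rho with transcript length was 0.153 in the FreeTir1 line and 0.206 in the Rps26Tir1 line, and with coding length 0.119 and 0.146. Among genes with average expression of at least 3, the longest decile of transcripts (median 7778 bases) had median fold changes of 0.09 in the FreeTir1 line and 0.12 in the Rps26Tir1 line. The lowest medians were not in the shortest decile, at 0.00 and -0.02, but at median lengths of 1890 bases in the FreeTir1 line, at -0.03, and 1442 bases in the Rps26Tir1 line, at -0.04. Genes that passed in the Rps26Tir1 line had a median transcript length of 4333 bases when positive and 2108 bases when negative, against 2881.5 bases for all genes. The difference between the lines had rho = 0.0992 with transcript length and 0.063 with coding length.

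**Figure D3:**
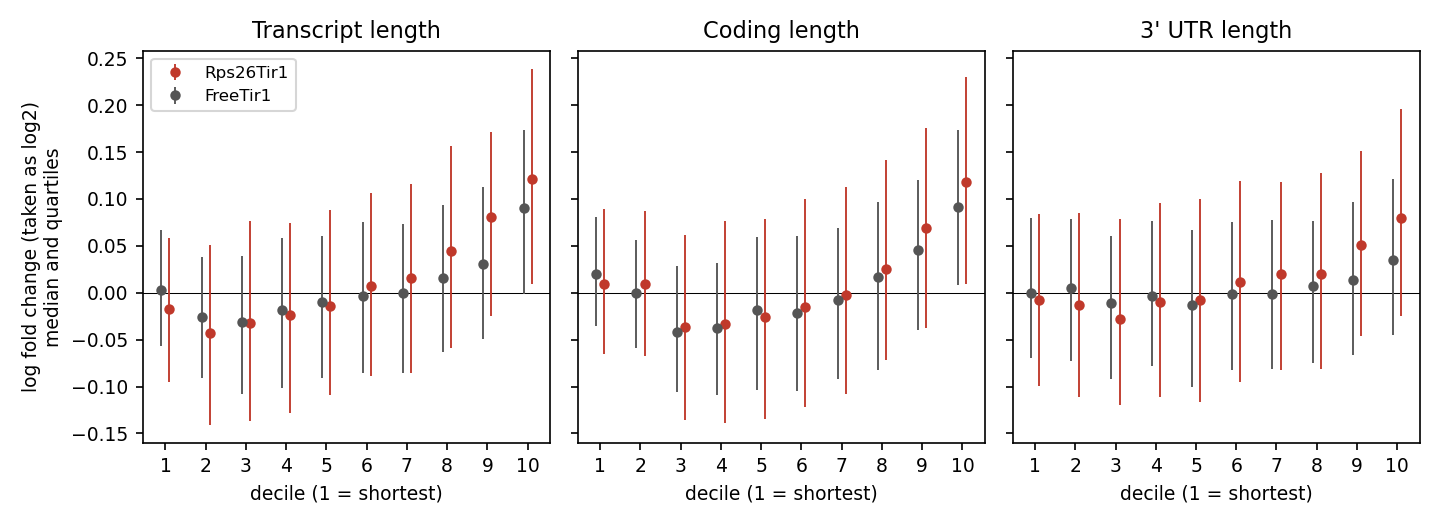
Median deposited log fold change (y axis, taken as log2; bars span the quartiles) in deciles of transcript, coding and 3' UTR length (x axis, 1 is the shortest) for 8633 genes with average expression of at least 3, red for the Rps26Tir1 line and grey for the FreeTir1 line. Medians in the longest decile of coding length are 0.12 and 0.09, and in the longest decile of 3' UTR length 0.08 and 0.04.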

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

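The tests of the difference between the lines, of the Rnaset2b copies, of standard errors and of signs across lines were chosen after the result was seen, and the count of shared sequence over the 222 genes after the table but before its own result. Rnaset2b was the gene whose effect differed between the lines, with adjusted p = 0.0414, and with 20 degrees of freedom or the trend in length, GC content and expression removed 0 genes differed. In the authors' deposited table its log fold change was 0.41 in the FreeTir1 line and -1.95 in the Rps26Tir1 line. Of its 31-base stretches 91.6% occur in transcripts of other genes, and its copy Rnaset2a, with 4.67 against 2.06 in average expression, had -0.14 and 0.12 in the authors' deposited table. The summed level of both copies moved by -0.18 in the Rps26Tir1 line with a standard error of 0.0943, where a change of Rnaset2b alone would give -0.29 and reads that only moved between the copies would give 0. Reads divided differently between the copies and a change of Rnaset2b itself cannot be told apart by that sum.

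As sets, 3 lists differed between the lines. They were p53 targets with adjusted p = 0.000608, nuclear-encoded oxidative phosphorylation genes with adjusted p = 0.000608 and glycolysis genes with adjusted p = 0.0298. In the FreeTir1 line their medians were 0.03, 0.03 and 0.00, and in the Rps26Tir1 line 0.24, -0.05 and -0.15. No member of these lists passed the difference test over all genes or when adjusted over the list alone. With a preset correlation of 0.05 the p53 targets held at adjusted p = 0.0429, whereas oxidative phosphorylation and glycolysis genes no longer passed, at 0.143 each, nor with the trend in length, GC content and expression removed, at 0.254 and 0.183.

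The pattern was 222 genes past the threshold in the Rps26Tir1 line and 0 in the FreeTir1 line. Larger standard errors in the FreeTir1 line are argued against. With the Rps26Tir1 standard errors in place of its own, 2.70% of the 222 genes would have reached the p of the least significant of them, against 1.8% with its own. The standard errors of the lines were nearly equal, with a median ratio of 1.01 over all genes, as a common model would give. Under such a model extra noise in the FreeTir1 libraries alone would not show in them, so it is not excluded. Reads shared between copies are argued against for the set as well, since 5.86% of the 222 genes had over 50% shared sequence, and 4.30% of the other genes did. The FreeTir1 median of these genes in the called direction was 0.189 and 82.4% had the same sign there, where 1000 draws from the relation between the lines among the other genes gave 0.131 to 0.180 and 73.4 to 82.4% (the middle 95% of draws, with genes drawn independently). A smaller change in both lines and a change in the Rps26Tir1 line alone with errors shared between the lines therefore cannot be told apart, since that relation may hold shared errors as well as shared effects.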

How the results depend on the processing

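All alternatives except the minimum fold change were chosen after seeing the data. No paired analysis was possible because the table holds no values per library; for the same reason the alternatives fixed in advance with other normalization, filters on counts, other tools, fewer libraries in the model, replicate or gradient blocks, left-out libraries or gradients, other fractions, summed fractions, estimated correlation and pseudocounts were not run, and depth cannot be judged.

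The 222 genes of the Rps26Tir1 line became 41 with an absolute fold change of at least 1, 528 at an adjusted p of 0.1, 90 with average expression of at least 3 and 143 with the trend in length, GC content and expression removed, of which 133 were among the 222. They numbered 179 to 209 under the remaining settings, with 110 positive and 77 negative when centred on the median gene. The 0 genes of the FreeTir1 line became 2 at 0.1 and stayed 0 under the others run. The 1 gene that differed between the lines became 0 with 20 degrees of freedom, with average expression of at least 3, without genes of over 50% shared sequence and with the trend removed, 2 with 40 degrees of freedom, 9 at 0.1, and 44 when the statistic was divided by 0.850, its spread over genes with average expression of at least 3. Of those 44, 39 had average expression below 3, where the spread was 1.22 for genes from 1 to 3 and 1.36 below 1. The cause was not tested beyond the construction of each setting.

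Of the 9 list results that passed, those for p53 targets held under all 5 alternatives in the Rps26Tir1 line and in the difference. With a preset correlation of 0.05 the adjusted p rose to 0.317 and 0.232 for pluripotency genes (FreeTir1, Rps26Tir1), 0.232 and 0.143 for oxidative phosphorylation (Rps26Tir1, difference), 0.196 and 0.143 for glycolysis (Rps26Tir1, difference) and 0.0617 for the proteasome. With the trend removed it was 0.180 and 0.254 for oxidative phosphorylation, 0.0859 and 0.183 for glycolysis and 0.0759 for the proteasome, while cytosolic ribosomal proteins (FreeTir1) passed at 0.00735, primitive endoderm markers (Rps26Tir1) at 0.00788 and immediate early genes (Rps26Tir1) at 0.0483. The rank-based form let pass mitochondrial ribosomal proteins, primitive endoderm markers and G2/M genes in the Rps26Tir1 line, each at 0.0405, and in the difference other 5' TOP mRNAs at 0.0416 and the proteasome at 0.0118. Average expression of at least 3 gave 0.0519 for pluripotency genes (FreeTir1), 0.0381 for mitochondrial ribosomal proteins, 0.0496 for G2/M genes and 0.0291 for the proteasome difference; of at least 1, 0.0447 for mitochondrial ribosomal proteins and 0.0386 for mesendoderm markers. The cause was not tested.

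With average expression of at least 1 and 3, the correlation between the lines rose to 0.283 and 0.474 (Pearson) and 0.378 and 0.459 (Spearman). The Spearman correlation with transcript length rose to 0.189 and 0.211 (FreeTir1), 0.260 and 0.287 (Rps26Tir1) and 0.132 and 0.15 (difference), and with coding length to 0.156 and 0.180 (FreeTir1) and 0.183 and 0.195 (Rps26Tir1). For 26 named genes and 4 alternatives, 94 values kept direction and side, 10 ended a call and 0 changed sign.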

Other observations

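All tests in this part, trend removal included, were chosen after the data were seen. In all, 11 families were inspected, and adjusted p covers all 11, which does not correct for choosing families after seeing the same values. Among genes of SR splicing factors, 4 of 11 passed in the Rps26Tir1 line: Srsf2, Srsf3, Srsf5 and Srsf7 stood at 0.49, 0.44, 0.48 and 0.49 in the authors' deposited table. Of the 31-base stretches of Srsf3 and Srsf5, 37.6% and 36.7% occur in other genes. The family had a median of 0.13 in that line, with adjusted p = 0.00236, and 0.0275 with a preset correlation of 0.05, against a median of 0.07 and adjusted p = 0.247 in the FreeTir1 line. The difference between the lines was positive for 9 of 11 genes, with adjusted p = 0.0446, and 0.350 with a preset correlation of 0.05. Zinc finger genes with Zfp symbols had a median of 0.12 over 338 genes in the Rps26Tir1 line, where 11 passed, all positive, and 0.02 in the FreeTir1 line. Their set test gave adjusted p = 0.00139 in the Rps26Tir1 line and 0.0446 for the difference, and 0.153 and 0.488 with a preset correlation of 0.05.

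The 2043 genes whose first 35 codons encode a hydrophobic stretch, as signal peptides do, had medians of -0.05 in the FreeTir1 line and -0.03 in the Rps26Tir1 line. Adjusted p was 0.0349 and 0.0789, and 0.480 and 0.512 with a preset correlation of 0.05. Among the other families, Kdm genes passed in both lines, with medians of 0.12 and 0.07 and adjusted p of 0.0128 and 0.0151 (FreeTir1, Rps26Tir1). The 4 Id genes had a median of 0.42 in the Rps26Tir1 line with adjusted p = 0.0203. Psm genes, nearly the proteasome list again, had adjusted p = 0.000574 there and 0.0446 for the difference. For the difference, the unadjusted p of the set test was 0.0088 for Psm genes and 0.0090 for the proteasome list. That list did not pass, with adjusted p = 0.0524. The adjustment covered 11 families for Psm genes and 29 lists for the proteasome list. The Psm result is therefore not separate evidence for a difference. With a preset correlation of 0.05, Kdm genes had adjusted p of 0.1004 and 0.0710 and Id genes 0.0503. At that correlation Psm genes had 0.0275 in the Rps26Tir1 line and 0.351 for the difference. The proteasome list, adjusted over more sets, had 0.0617 in the Rps26Tir1 line at that correlation and did not pass. The Hnrnp, Clk, Dnaj, Slc and Tmem families passed in no comparison, with adjusted p from 0.102 to 0.975.

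Fold changes were higher for longer transcripts in both lines. With the trend in length, GC content and expression removed, 59.9% of the 222 genes stayed past the threshold, which does not decide whether the trend may account for the rest. The median absolute fold change of the 89 genes that were lost went from 0.50 to 0.46 with a standard error of 0.132, so they were close to the threshold. Of these 89 genes, 10 were also lost when only the adjustment was recomputed over the genes in the table, with the trend left in. Coding length as a source of the difference between the lines stays open: over 8633 genes with average expression of at least 3, with UTR lengths and expression held fixed, its partial rank correlation with the difference was 0.047, and that of 3' UTR length 0.13. Within the lines, the partial correlation with coding length was 0.173 and 0.168 (FreeTir1, Rps26Tir1), and that with 3' UTR length 0.0351 and 0.144.

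For the 1983 genes with average expression above 6, the variance of the FreeTir1 fold changes was 0.0101 and their mean squared standard error 0.0119, while the covariance with the Rps26Tir1 fold changes was 0.00903. The difference statistic had a robust spread of 0.689 in these genes and 1.36 in the 2313 genes below 1, where 1 is the value with no difference, independent errors of the lines and correct standard errors. The count of genes that differ between the lines rests on those assumptions, which the values above 6 go against.

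Several symbols stood for a pair of overlapping gene models. Nnt had -1.01 and 6.2 in the Rps26Tir1 column of the authors' deposited table, with adjusted p of 0.186 and 0.169, and Ptp4a1 had 3.74 and 0.13 with adjusted p of 0.115 and 0.623 there. Both models of each share over 90% of their 31-base stretches with other genes.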
